A study of Zea mays with 4 samples.

How the data were processed

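The study profiled microRNAs in leaves of 4 maize samples, namely CK1 and CK3 (unfed), T1 (1 day of feeding by *Spodoptera frugiperda*) and T3 (3 days). Per the labels' protocols, total RNA was extracted with Trizol, and small RNA libraries were prepared with the TruSeq Small RNA kit and sequenced on an Illumina HiSeq instrument. The labels give no replicate of any group and do not say when the unfed leaves were taken. The protocol speaks of more libraries than the 4 samples analysed here, and nothing says whether a value column stands for a single library or pools several. Per the file headers, the deposited values are normalized signal values per microRNA sequence, scaled by the authors. The scaling method, aligner, microRNA caller and genome build are not given in the sources used here. Names and their suffixes are printed as in the table.

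The table held 500 rows with 319 different sequences of 18 to 25 nt, and rows of the same sequence had equal values in every library. Each sequence was used once, under a maize name where one existed. Entries with equal values in all 4 libraries whose names differed only in a final number, or whose sequences contained one another, were merged, which left 307 entries. The names covered 65 families. Within a library 90.0% to 93.6% of the values above 0 were whole multiples of a single step, within 0.02 of a read, and the others were fractions of it. The step was taken as the largest for which at least 85% of low values were whole multiples, a share that had been lowered after a stricter one gave no step. The step served as the value of 1 read and gave the relative depth of the listed entries, which spanned 2.43-fold. The sums over listed entries are not the total depth of the libraries, which was not used here. Because part of the values were not whole, no count model was applied. Hardly any value stood below 5 reads. Intervals from implied reads cover counting error only, and reads without molecular identifiers are not independent molecules.

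The design fixed before the data were examined foresaw counts, with a log-scale plan for a table of normalized values, and the latter was used. Ratios are log2(value + 1) differences. These understate the ratio of low entries listed in both libraries, but can overstate it where an entry is listed at 0, since a 0 can hide a value up to the level of 5 reads (3.68 units in CK1 and 4.13 in CK3). Between single libraries an entry was called higher or lower by size alone, with at least a 2-fold difference on that scale and at least 10 normalized reads in the higher library. No test was made there. Fed against unfed libraries (2 against 2) were compared with limma with a trended prior on entries with at least 10 normalized reads in at least 2 libraries, at an adjusted p (Benjamini-Hochberg) of 0.05. The spread in that test includes the difference between feeding times and that between the unfed libraries, and nothing says that the libraries came from separate plants, so its p-values measure the spread between these 4 samples. Family totals sum all members of a family, which can share reads.

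The lists of families by textbook target (growth and leaf development, auxin signalling, small RNA machinery, copper proteins and laccases, sulfate and phosphate nutrition, phasiRNA triggers and NBS-LRR regulators) and a list of insect microRNAs were fixed before the data were examined. A list's median ratio was placed among 10000 random lists of the same size matched on abundance, and for fed against unfed the lists were tested with camera at a correlation of 0.01 and with an estimated one. The entries named were, by a rule fixed before the data were examined, the 10 largest log2 ratios in each direction per comparison with the matched control, the 5 most abundant entries, the listed families, and the 5 smallest p of the limma test where none passed. The names used as candidates for ribosomal or transfer RNA fragments (miR5368, miR6173, miR4995, miR6300, miR8175, miR6478, miR5072 and miR5077) were chosen after the values were seen, many because they stood high in CK3. Their origin was not checked against a genome, and 49 entries carry them. The random lists were drawn from all compared entries, these included.

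The limma step was tested on simulated data for the 307 entries. The same 40 entries were changed in each of 20 runs, drawn from the 147 that passed the minimum for the test. The dispersion was 0.1. This dispersion was set and not estimated from these libraries. Between CK3 and CK1 the log2 ratios of entries listed in both had an SD of 1.27, and the simulated spread was not matched to it. The shares recovered therefore do not give the power of the test on these data. The test recovered 19% of 2-fold and 99.5% of 8-fold increases, and 74% of 4-fold and 86% of 16-fold decreases, with 0.55 false calls per run. Each size was simulated in 1 direction only, so size and direction cannot be told apart in these shares. Alternatives were other scalings (equal totals, median of ratios), other minimum values (none, 100), other pseudocounts (0.1, 10), maize names only, the other control or the mean of both, and leaving out each library in turn. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.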

Results

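Small RNA libraries were made from leaves of maize plants at the 4-leaf stage, to profile microRNAs while larvae of *Spodoptera frugiperda*, the fall armyworm, fed on the plant. There were 4 libraries, each the only one of its group analysed here. T1 came from leaves after 1 day of feeding and T3 from leaves after 3 days. CK1 and CK3 are the unfed libraries, whose labels give only the tissue. Each fed library was compared with the unfed library of the same title number. The table held 307 entries (distinct mature sequences after merging), of which 110 had maize names, 156 had names from other plants and 41 were predicted. None carried the name of an insect microRNA on the list fixed beforehand. The listed entries summed to 59320 normalized reads in CK1, 69028 in CK3, 59335 in T1 and 59687 in T3. The steps between values corresponded to 80609 reads in CK1, 83592 in CK3, 195983 in T1 and 169533 in T3. In CK1 1 read was worth 0.736 units, against 0.826 in CK3, 0.303 in T1 and 0.352 in T3, and nearly all listed values stood for at least 5 reads. Entries above 0 numbered 194 in CK1, 190 in CK3, 269 in T1 and 264 in T3, so an entry listed at 0 can still have been present below this limit. With 1 library per group, no difference between single libraries has a replicate check, and none of those counts has a p-value.

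**Figure D1:**
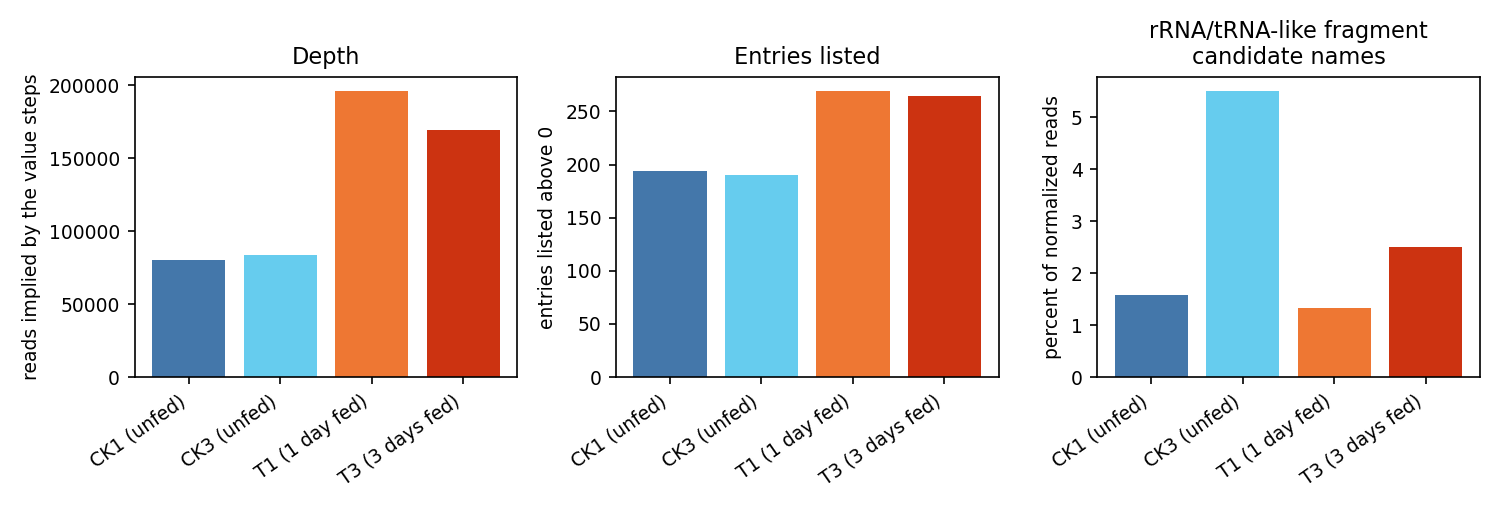
Bars give, for each of the 4 libraries, the reads implied by the value steps, the number of entries listed above 0, and the percent of normalized reads under names that are candidates for ribosomal or transfer RNA fragments. The fed libraries listed 269 and 264 entries against 194 and 190 in the unfed ones. The fragment candidates, many of them chosen because they stood high in CK3, took 5.50% in CK3 against 1.34% to 2.50% in the other libraries.

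The most abundant entries were 3 of miR9774, a family named in wheat, and their sequences differed from one another only at the ends. Together with its other entries the family held 57.4% of the normalized reads in CK1, 63.4% in CK3, 58.2% in T1 and 55.4% in T3. The leading member, tae-MIR9774-p5_2ss4AG21GT, reached 15820, 21284, 17449 and 17711 normalized reads in the same order, tae-MIR9774-p3_2ss4AG21GT 12110, 14678, 11781 and 10290, and tae-MIR9774-p3_2ss5AG22GT_2 4588, 5353, 3823 and 3699. Next came zma-miR168b-3p_R+1, of the family that targets the Argonaute protein AGO1, at 3889, 3005, 3444 and 3908 normalized reads, and zma-miR408a, of a family that targets copper proteins, at 2641, 3844, 3110 and 3332. AGO1 is named here as the target of the family and not of the 3p entry itself.

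After 1 day of feeding, no family on the fixed lists differed by 2-fold from CK1 among the 26 compared. The copper and laccase regulator miR397 had the largest positive log2 ratio of these, 0.74, from 1202 normalized reads in CK1 to 2008 in T1. The Cu/Zn superoxide dismutase regulator miR398 had a log2 ratio of 0.50 and the nuclear factor Y regulator miR169 one of 0.42. The auxin response factor regulator miR160 was at 783 in CK1 and 534 in T1, a log2 ratio of -0.55, miR171, which targets GRAS factors, stood at -0.54, the DCL1 regulator miR162 at -0.69 and the NBS-LRR regulator miR482 at -0.75. The TCP regulator miR319, with 6.62 and 10.6 normalized reads, had a log2 ratio of 0.61. Against CK3 in place of CK1, miR162, miR172, miR319 and miR399 were over 2-fold higher in T1 and miR2118 was over 2-fold lower. The log2 ratio to CK3 was -0.28 for miR397, 0.0007 for miR398, 0.03 for miR169, 0.83 for miR160, 0.33 for miR171 and -0.54 for miR482. The sign thus changed for miR397, miR160, miR171 and miR162.

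Among single entries, 25 were at least 2-fold higher in T1 than in CK1 and 17 at least 2-fold lower, of 159 with at least 10 normalized reads in either library. Of the 10 with the largest positive log2 ratios, 9 were listed at 0 in CK1. They were osa-miR5072_L-4 at 16.3 normalized reads in T1, zma-miR169m-3p_L+1 and zma-miR1432-5p_L-1R+1 at 15.1 each, aly-MIR4226-p5_2ss13AC18TG at 13.3, zma-miR169i-3p_R+2 and sbi-MIR169o-p3_2ss3CA18GT at 12.1 each, zma-miR156j-3p_L-1 at 10.9, and bdi-miR156b-5p_R+2 and osa-MIR2118k-p5_2ss5GA19TG at 10.3 each. The remaining one, zma-MIR169a-p3, was at 3.68 in CK1 and 17.3 in T1. In the other direction, PC-5p-59745_10, zma-MIR11970-p3_1ss16AG and PC-5p-40256_19 were at 14.7, 13.2 and 11.0 in CK1 and listed at 0 in T1. They were followed by gma-MIR6300-p3_1ss15AG with a log2 ratio of -2.10, zma-MIR171b-p5 with -1.89, zma-MIR160e-p3 with -1.67, htu-miR160a_R+1 with -1.48, zma-miR408b-5p_L+1 with -1.45, PC-5p-24810_36 with -1.39 and zma-miR171d-5p with -1.36. With CK3 as the control, 7 of the 25 higher entries and 3 of the 17 lower ones passed the same rule in the same direction, 3 of the higher entries were at least 2-fold lower, and the log2 ratios of zma-miR1432-5p_L-1R+1, bdi-miR156b-5p_R+2, zma-MIR171b-p5, zma-MIR160e-p3, htu-miR160a_R+1, zma-miR408b-5p_L+1 and PC-5p-24810_36 changed sign. Only 1 of the 45 entries with at least 100 normalized reads in either library passed the rule. It was gma-MIR5368-p3_2ss1AT18CA, a fragment candidate name, with a log2 ratio of -1.27, and it is named here after its values were seen.

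By list, 10 of the 62 compared members of the growth and leaf development families were higher in T1, 3 were lower and 49 were neither, with a median log2 ratio of 0.06, at percentile 82.7 of 10000 random lists of matched abundance. Against CK3 that list had 13 higher and 4 lower members and a median of 0.35, and over family totals against CK1 the median was -0.05. Of 20 auxin signalling members, 4 were lower and none was higher, with a median of -0.30 at percentile 14.5. Against CK3 that median was 0.18, with 3 of 18 members lower, and against the mean of both controls none was lower. Of 15 entries in the families that target copper proteins and laccases, whichever arm of the precursor they came from, 2 were higher and 1 was lower. Their median was 0.33 at percentile 97.0, and against CK3 it was -0.14. None of the 4 small RNA machinery members passed the rule, with a median of -0.19 at percentile 41.5. Against CK3 1 of the 4 was higher and the median was 0.37. Of 3 sulfate and phosphate nutrition members 1 was lower, with a median of -0.61 at percentile 11.2 and of 0.12 against CK3. Of 2 entries in the phasiRNA trigger and NBS-LRR regulator families 1 was higher, with a median of 1.38 at percentile 73.4. The higher entry, osa-MIR2118k-p5_2ss5GA19TG, was listed at 0 in CK1. Against CK3, 2 of 4 were lower and none was higher, with a median of -0.80, and the median was also negative against the mean of both controls (-0.65) and over family totals (-0.41).

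After 3 days of feeding, 7 of 26 listed families were at least 2-fold higher in T3 than in CK3. The HD-ZIP III regulator miR166 was at 1154 normalized reads in CK3 and 2347 in T3, a log2 ratio of 1.02. The NAC regulator miR164 was at 236 and 492, the auxin response factor regulator miR160 at 300 and 696, and the TCP regulator miR319 at 2.06 and 11.4. The families miR162, which targets DCL1, miR172, which targets AP2-like factors, and miR399, which targets the phosphate regulator PHO2, were listed at 0 in CK3 and at 33.1, 38.4 and 19.0 in T3. The phasiRNA trigger miR2118 was lower, at 57.0 in CK3 and 16.2 in T3. Against CK1, none of the 26 families differed by 2-fold in T3: CK1 held 1759 normalized reads of miR166, 453 of miR164, 783 of miR160, 42.7 of miR162, 30.5 of miR172 and 11.8 of miR399. Under median-of-ratios scaling, miR164 and miR166 fell short of 2-fold and miR397 was over 2-fold lower.

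**Figure D2:**
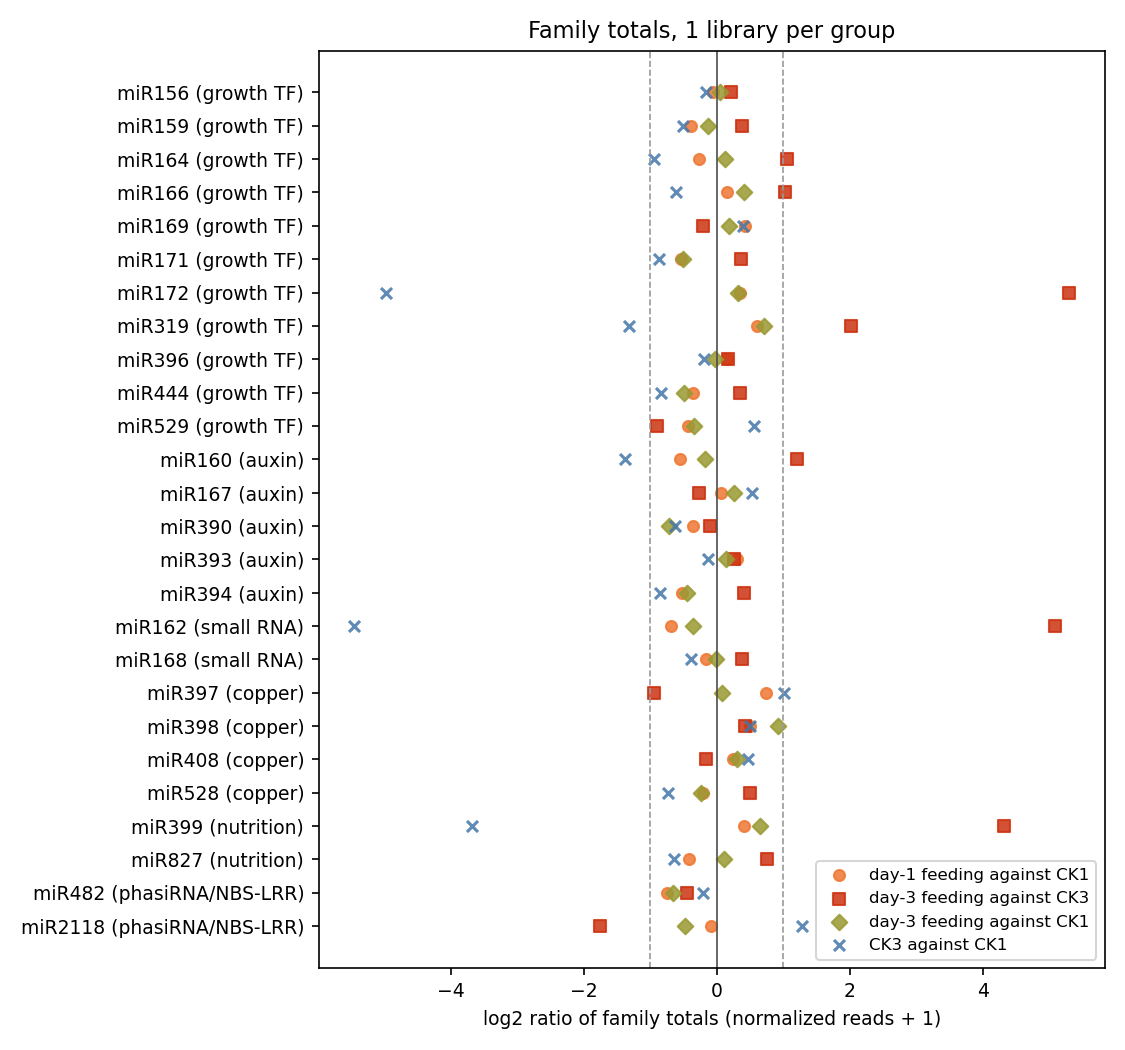
Each row is a microRNA family on the fixed lists with at least 10 normalized reads in a library, and each symbol is the log2 ratio of its total (plus 1) between a pair of libraries, with 1 library per group and dashed lines at 2-fold. The ratios of T3 against CK3 for miR162, miR172 and miR399 lie at 5.09, 5.30 and 4.32, where CK3 was listed at 0, and those against CK1 lie at -0.36, 0.32 and 0.65.

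Among single entries, 44 were at least 2-fold higher and 35 at least 2-fold lower in T3 than in CK3, of 173 compared. The 10 with the largest positive log2 ratios were all listed at 0 in CK3. They were osa-MIR6253-p5_2ss5AC17TA at 33.1 normalized reads in T3, zma-miR162-3p_R+1 at 29.6, osa-miR5082_R-1_1ss1TC at 23.2, PC-3p-17806_53 at 20.4, zma-miR159c-3p_L-1R-1 at 17.3, aof-MIR8155-p3_1ss5CA at 16.9, sbi-MIR169o-p3_2ss3CA18GT at 16.2, osa-miR5072_L-4 at 15.5, and osa-miR166a-3p_R+1 and PC-5p-28290_30 at 12.0 each. In the other direction hbr-miR6173_R+2, zma-miR2118b, zma-miR156i-3p and aly-miR396b-5p_R+1 were at 24.8, 14.9, 11.6 and 11.6 in CK3 and listed at 0 in T3. They were followed by hbr-MIR6173-p5_1ss7TG with a log2 ratio of -3.36, hbr-MIR6173-p3_1ss4CT_3 with -2.90, gma-MIR6300-p3_1ss15AG with -2.80, gma-miR6300_L-1R+8 with -2.64, gma-miR6300_R+7_2 with -2.19 and hbr-miR6173 with -2.13. Of the 35 lower entries, 21 carried a name of a fragment candidate, against 37 of the 173 compared, but many of these names were chosen for their level in CK3. With CK1 as the control, 15 of the 44 higher entries and 2 of the 35 lower ones passed the same rule in the same direction. By contrast, 2 of the higher entries were at least 2-fold lower and 6 of the lower entries at least 2-fold higher. The log2 ratios of zma-miR162-3p_R+1, hbr-MIR6173-p5_1ss7TG, hbr-MIR6173-p3_1ss4CT_3, gma-miR6300_R+7_2 and hbr-miR6173 changed sign. Scaling the libraries to equal totals moved the median log2 ratio of all compared entries from 0.09 to 0.31 and gave 52 higher and 29 lower entries, while median-of-ratios scaling moved it to -0.03 and gave 41 higher and 40 lower.

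By list, 22 of 65 growth and leaf development members were higher in T3 than in CK3, 6 were lower and 37 were neither. Their median log2 ratio was 0.44, at percentile 96.8 of the random lists, which could hold fragment candidates. Without the candidates, all 136 entries compared had a median of 0.35, with 42 higher and 14 lower, close to the list. Against CK1 the same list had 9 higher and 3 lower members and a median of 0.03. Of 19 auxin signalling members, 3 were higher and 2 were lower, with a median of -0.002 at percentile 47.3, and of 0.21 at equal totals. Against CK1 none of 20 was higher and 2 were lower, with a median of -0.08, and against the mean of both controls none passed the rule. Of 14 copper and laccase members, 3 were higher and 2 lower, with a median of -0.09 at percentile 34.5, which was 0.07 against CK1 and 0.12 at equal totals. Of 4 small RNA machinery members 1 was higher, with a median of 0.55 at percentile 83.5, but none of the 4 against CK1, where the median was -0.07. Neither of the 2 nutrition members passed the rule, with a median of 0.55 at percentile 85.6 and of -0.29 against CK1. Of 3 entries in the phasiRNA trigger and NBS-LRR regulator families 2 were lower, with a median of -1.12 at percentile 11.2. Against CK1 neither of the 2 compared passed the rule, with a median of -0.16.

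Of 175 entries compared, 45 were at least 2-fold higher in CK3 than in CK1 and 40 at least 2-fold lower, or 48.6% of those compared, against 26.4% for T1 and CK1 and 45.7% for T3 and CK3. Whether CK3 and CK1 or T3 and CK3 had the larger share depended on the entries used. With no minimum value the shares were 55.9% for CK3 and CK1, 47.9% for T1 and CK1 and 58.6% for T3 and CK3. Without the fragment candidates CK3 and CK1 had 41.7% and T3 and CK3 41.2%, and with maize names only both had 39.0%. The families miR160, miR162, miR172 and miR399 were at least 2-fold lower in CK3, the last 3 listed at 0 there, and miR2118 and miR397 were at least 2-fold higher, miR397 at 2438 normalized reads against 1202. Of 61 growth and leaf development entries, 7 were higher and 16 lower, with a median log2 ratio of -0.55 at percentile 0.45. The random lists behind this percentile could hold fragment candidates. Without the candidates, all 139 entries compared had a median of -0.45, with 18 higher and 40 lower, close to the list. The medians of the other lists were -0.48 for auxin signalling, 0.08 for copper and laccases (-0.13 at equal totals), -0.43 for the small RNA machinery, -0.65 for nutrition and 0.92 for the phasiRNA triggers. Fragment candidates made up 27 of the 45 higher entries and none of the 40 lower ones, against 36 of the 175 compared. Many of these names were chosen because they stood high in CK3, so this split was partly set by the choice. The summed values of the candidates included 2113 normalized reads of miR5368 in CK3, against 393 in CK1, 381 in T1 and 809 in T3. They also included 415 of miR6173, against 39.0, 21.2 and 78.2. Equal totals turned the balance to 39 higher and 51 lower entries and moved the median log2 ratio of all compared entries from 0.15 to -0.115.

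The fed libraries were the closest pair, with a correlation across 192 entries of 0.934 (Pearson's r of log2 values; entries are not independent replicates), against 0.883 for T1 and CK1, 0.804 for T3 and CK3, 0.863 for T3 and CK1, 0.785 for T1 and CK3, and 0.727 for CK1 and CK3. T3 was thus closer to CK1 than to the control of its own number. The fed libraries were also the deepest, with over 2 times the implied reads of either unfed one. The correlations include entries listed at 0 in a library. Over the 70 entries with a mean of at least 50, the SD of log2 ratios was 0.53 for T3 and T1. It was 0.59 for T3 and CK1 and 0.61 for T1 and CK1, so the fed pair was only slightly closer there. The pairs with CK3 had 0.92 (T3), 1.18 (CK1) and 1.21 (T1). Between T3 and T1, 20 entries were at least 2-fold higher at day 3 and 6 at least 2-fold lower, of 158 compared. Of the 20 higher entries, 9 carried fragment candidate names, against 24 of the 158 compared. One of the 9 was gma-MIR5368-p3_2ss1AT18CA, at 55.1 in T1 and 174 in T3. Among the 6 lower ones were zma-MIR169c-p5, at 96.2 and 43.1, and zma-miR156i-3p, at 10.3 in T1 and listed at 0 in T3. These entries were picked after their values were seen.

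The log2 ratios of the feeding comparisons were nearly unrelated. Across 140 entries compared at both times, Pearson's r was 0.150 and Spearman's rho 0.027, a description over entries that are not independent replicates. The entries higher at both times numbered 8, where independent lists would share 5.43. They were zma-miR159a-5p, zma-miR164e-5p, zma-MIR169i-p3, sbi-MIR169o-p3_2ss3CA18GT, vvi-MIR3630-p5_2ss18AT19CT, osa-miR5082_R-1_1ss1TC, osa-MIR6256-p5_2ss10GC17TA and osa-miR5072_L-4. The 3 entries lower at both times, where 0.73 would be shared, were gma-miR4995_L-2R+4, gma-MIR5368-p3_2ss1AT18CA and gma-MIR6300-p3_1ss15AG, all with fragment candidate names. With the controls exchanged, Spearman's rho was -0.14.

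**Figure D3:**
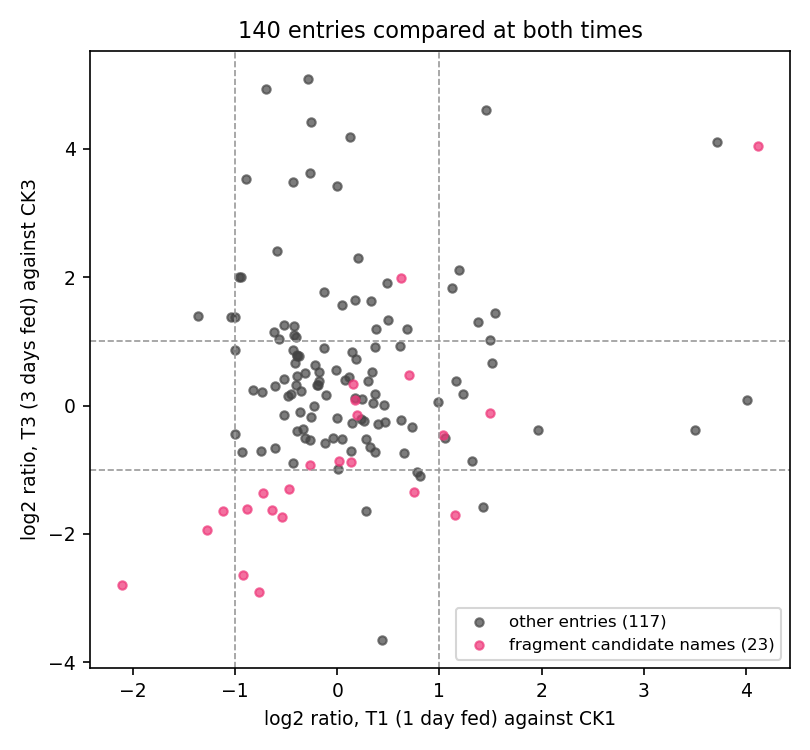
Each point is 1 of 140 entries compared at both times, with the log2 ratio of T1 against CK1 on the horizontal axis and of T3 against CK3 on the vertical axis, dashed lines at 2-fold and fragment candidate names in colour (23 entries). The ratios do not line up, with a Pearson's r of 0.150.

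Over all 4 libraries, no entry passed the test of fed against unfed. The entries with the smallest p had the following values. osa-miR5072_L-4 was listed at 0 in both unfed libraries and at 16.3 and 15.5 in T1 and T3. sbi-MIR169o-p3_2ss3CA18GT was listed at 0 in both and at 12.1 and 16.2. zma-miR164e-5p, a NAC regulator, was at 13.2 and 19.8 in CK1 and CK3 and at 40.6 and 55.6 in T1 and T3, a log2 difference of 1.49 ± 0.51 (SE), and osa-MIR6256-p5_2ss10GC17TA had one of 1.34 ± 0.46. gma-MIR6300-p3_1ss15AG was at 22.8 and 20.6 in the unfed and at 4.54 and 2.11 in the fed libraries, a log2 difference of -2.45 ± 0.67. Their adjusted p by limma lay between 0.54 and 0.85, over 147 entries. Of these 147, 7 had an unadjusted p under 0.05, where 7.35 would be expected by chance. With no minimum value 35 of 307 entries did, where 15.35 would be expected, and again none was called, with a smallest limma adjusted p of 0.26. The entries added without a minimum are low, and some are listed at 0 in both unfed libraries, which leaves no spread there. The limit of 5 reads, higher in the unfed libraries, can produce such values. This fit was not repeated with values raised to that limit. With a fed library left out, the spread comes from CK1 and CK3 alone. Without T1 the test called sbi-MIR169o-p3_2ss3CA18GT and osa-miR5072_L-4 higher and zma-miR156i-3p lower, and without T3 it called the miR169 and miR5072 entries higher. Both unfed libraries list these entries at 0, so their own spread there was 0, which the limit on low values can produce. The fits with a library left out were not repeated with values raised to that limit. For zma-miR156i-3p, T3 was listed at 0, while T1, at 10.3, lay between CK1 at 7.36 and CK3 at 11.6. osa-miR5072_L-4 and gma-MIR6300-p3_1ss15AG carry fragment candidate names. Of 192 entries, 27.6% had both fed libraries on the same side of both unfed ones, 34 above and 19 below, where chance gives 33.3%.

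Family totals gave no call among 44 families, with 4 at an unadjusted p under 0.05. The smallest limma adjusted p was 0.05003, for miR5072, with a log2 difference of 4.08 ± 0.45 (SE) and both unfed values listed at 0. This family held 1 entry, osa-miR5072_L-4, so its total repeats the values of that entry. Tested among the single entries, the same values had an SE of 0.87 and a limma adjusted p of 0.54. None of the 6 fixed lists passed camera. In the growth and leaf development list 41 of 57 tested members had a higher mean in the fed libraries, with a median log2 difference of 0.20, a camera adjusted p of 0.20 and an adjusted p of 0.91 with an estimated correlation. The phasiRNA list had 2 tested members, both lower, and a camera adjusted p of 0.20. The auxin, copper, small RNA machinery and nutrition lists had camera adjusted p of 0.69, 0.86, 0.67 and 0.86. Adjusted over the list alone, no member of any list was called.

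**Figure D4:**
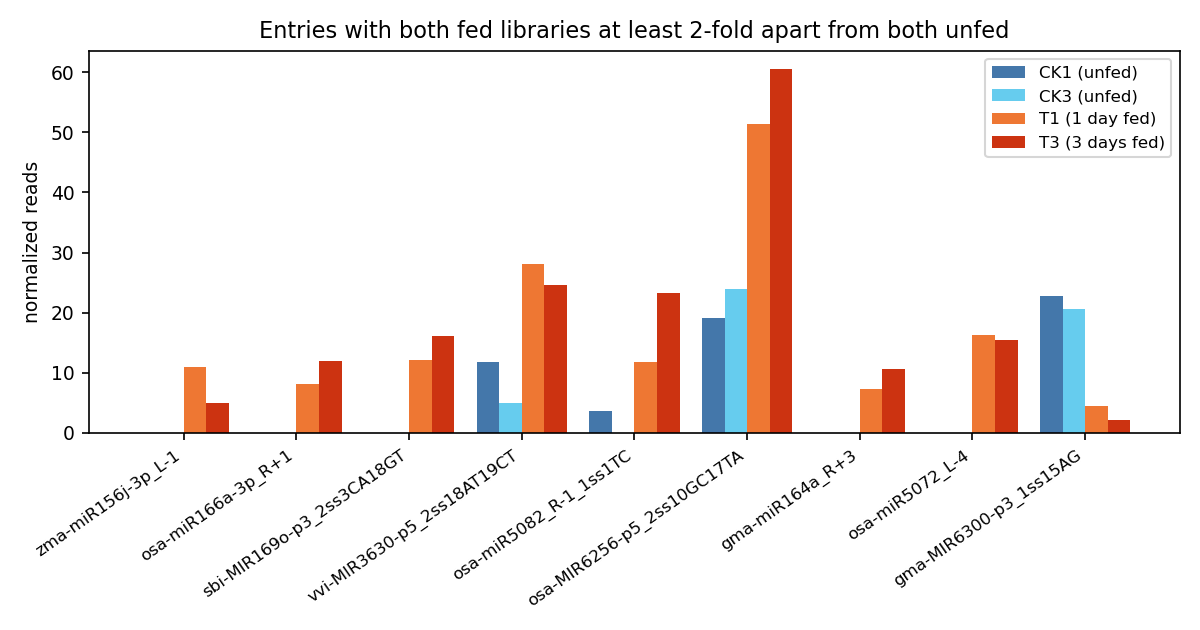
Bars give the normalized reads of the 9 entries for which both fed libraries lay at least 2-fold from both unfed ones on the log2 scale after adding 1. The entry highest in the fed libraries, osa-MIR6256-p5_2ss10GC17TA, stood at 51.5 and 60.6 there against 19.1 and 23.9 in the unfed ones.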

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

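Of the tests in this part, only the one on sequencing depth was written before its result was seen. All the others were chosen after related values had been seen.

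In 4 entries the feeding comparisons went in opposite directions, each by at least 2-fold. The difference was not tested, and each comparison has 1 library per group. For zma-miR171d-5p the log2 ratio was -1.36 at day 1 and 1.39 at day 3, a difference of 2.75. For aof-miR408_R+1_2ss19GT20CT it was 1.43 and -1.58, a difference of -3.01, with 61.1 normalized reads in CK3 and 8.83 to 25.4 in the other libraries. The fragment candidate gma-MIR5368-p3_1ss14CA had 1.15 and -1.71, a difference of -2.86, with 126 in CK3 and 7.36 to 38.0 elsewhere. The predicted PC-3p-12223_82 had -1.04 and 1.38, a difference of 2.41.

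CK3 stood apart from the other 3 libraries. Rescaling did not remove this. Under both other scalings the share of entries called between CK3 and CK1 stayed at least 1.852 times that of the day-1 comparison. Median-of-ratios scaling hardly moved CK3 against CK1, with log2 factors of 0.019 and 0.015. Equal totals used log2 factors of -0.159 for CK3 and 0.060 for CK1. The values therefore argue only against a scaling error that these methods would correct. Reads taken up by fragment candidates could lower other entries. Without them and at equal totals, however, the 107 fixed-list entries still had a median log2 ratio of -0.632. Those totals still held miR9774, at 34062 normalized reads in CK1 and 43788 in CK3. At equal totals its higher level lowers the rest of CK3, and that part of the ratio was not set apart. A leaf age or sampling time shared with T3 would, acting alone, lower the same entries there. The test covered 28 of the 40 entries lower in CK3, those with at least 10 normalized reads in a fed library. Their median log2 ratio of T3 to T1 was 0.192 (SD 0.49), against -1.82 for CK3 to CK1. These values argue against age or sampling time acting alone on those entries. T3 was also fed for longer than T1, so an age effect offset by feeding cannot be told apart from no age effect. For 27 of the 45 higher entries the median log2 ratio of T3 to T1 was 0.934, and 16 of the 27 were fragment candidates. An age, sampling time or batch shared by the number-3 libraries stays open for the higher entries, and RNA degradation was not tested.

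More entries were listed in the fed than in the unfed libraries. With the implied reads thinned to the depth of the matched control, T1 kept a mean of 218 listed entries (range 210 to 225 in 100 draws) against 194 in CK1, and T3 220 (207 to 227) against 190 in CK3, at most 1.159 times the control. Depth may therefore account for most of the gap, and the value lay between the bounds set for it, so the remainder stays open. Entries with at least 10 normalized reads in both fed libraries and at 0 in both unfed ones numbered 2, osa-miR5072_L-4 and sbi-MIR169o-p3_2ss3CA18GT, against 0 for any other pair of libraries, too few to show that feeding adds microRNA species.

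In 9 entries both fed libraries lay at least 2-fold from both unfed ones, 8 higher and 1 lower. The pairing of number-1 against number-3 libraries also gave 9, and 2 of the 3 pairings reached that number. The 3 pairings are too few for a share under 0.05. With values raised to 4.13, the level of 5 reads in CK3 and the highest such level of the 4 libraries, 66.7% of the 9 entries were left, so a limit on low values could account for part of them.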

How the results depend on the processing

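Of 219 alternatives run for the comparisons, 154 kept their side of the threshold or stayed within 1.5 times the count or within the standard error of the median or correlation, and 65 moved. The standard error replaced the SD of a list's members as the spread for list medians after the values were seen, and with the SD the numbers were 164 and 55. The cause of the moves was not tested, except that stricter minimum values and name filters leave fewer entries. The alternatives with fragment candidates left out, values raised to the common floor, or implied-read intervals were chosen after seeing the data, and the fragment names were picked partly for their level in CK3. The common floor lies under the minimum of 10 and changed no count between libraries, so it says nothing about their stability. DESeq2, TMM scaling and raw values were not run, since the values are not counts.

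Higher and lower counts without a minimum were 103 and 31 for day 1, 113 and 47 for day 3, 66 and 62 for CK3 against CK1, and 57 and 42 for T3 against T1. With a minimum of 100 they were 0 and 1 for day 1, 5 and 11 for day 3, 15 and 6 for CK3 against CK1, and 2 and 0 for T3 against T1. With a pseudocount of 10 they were 15 and 5 for day 1 and 9 and 2 for T3 against T1, and the lower count at day 3 was 21. With maize names only they were 9 and 8, 23 and 7, and 9 and 23 for the first 3 comparisons, and T3 had 3 entries higher than T1. Without fragment candidates the lower count was 14 at day 3, and the higher count 18 for CK3 against CK1 and 11 for T3 against T1. With the other control the lower counts were 38 at day 1 and 13 at day 3. With the mean of both controls the higher counts were 15 and 24, and the lower count at day 3 was 14.

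For family totals, the other control gave 4 higher and 1 lower at day 1 and 0 and 0 at day 3. The mean of controls gave 3 higher at either time. The most abundant member gave 1 lower at day 1 and 2 at day 3, as did median-of-ratios scaling at day 3 with 2. Equal totals gave 1 higher and 8 lower for CK3 against CK1.

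List medians with the other control at day 1 were 0.347 for growth, 0.18 for auxin, 0.375 for small RNA machinery, -0.14 for copper and 0.123 for nutrition, and at day 3 0.027 for growth and -0.29 for nutrition. With the mean of controls they were 0.147 for small RNA machinery and -0.222 for nutrition at day 1, and 0.205 for nutrition at day 3. As family totals they were -0.428 for small RNA machinery and -0.002 for nutrition at day 1, 0.265 for auxin, 2.738 for small RNA machinery and 2.537 for nutrition at day 3, and -2.922 for small RNA machinery and -2.161 for nutrition in CK3 against CK1. A further 11 medians changed sign within the standard error, which is wide for short lists. They were -0.054 for growth as family totals at day 1, -0.414 as family totals, -0.795 with the other control and -0.654 with the mean of controls for the phasiRNA triggers at day 1, 0.205 for auxin at equal totals at day 3, -0.073 for small RNA machinery with the other control at day 3, 0.122, 0.132, 0.068 and 0.039 for copper at day 3 at equal totals, as family totals, with the other control and with the mean of controls, and -0.133 for copper at equal totals in CK3 against CK1. Spearman's rho with crossed controls was -0.139.

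Of the named entries, 13 values changed sign, 12 with the other control and 1 with the mean of controls. Against the other control the day-1 log2 ratios were -0.37 for zma-miR1432-5p_L-1R+1, -1.09 for bdi-miR156b-5p_R+2 (-0.15 with the mean of controls), 2.21 for zma-MIR171b-p5, 2.01 for zma-MIR160e-p3, 3.38 for htu-miR160a_R+1, 3.33 for zma-miR408b-5p_L+1 and 2.94 for PC-5p-24810_36. The day-3 ratios were -0.51 for zma-miR162-3p_R+1, 1.79 for hbr-MIR6173-p5_1ss7TG, 0.29 for hbr-MIR6173-p3_1ss4CT_3, 1.46 for gma-miR6300_R+7_2 and 2.73 for hbr-miR6173.

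In the limma test of fed against unfed, leaving out 1 library in turn gave 0 to 3 calls. Without CK1 it called 0, with 49 of 147 entries at an unadjusted p under 0.05, and without CK3 0, with 21. The lone library is then assumed to vary like the other arm. Without T1 and without T3 it called 3 and 2 entries, of which 2 rest on a spread of 0 between unfed libraries both listed at 0. The same-numbered libraries share only a title number. With the number as a replicate block there were 0 calls, 8 entries at an unadjusted p under 0.05 and a smallest adjusted p of 0.73, and the deviations of same-numbered libraries correlated at 0.28. The block changed no call of the lists or families. The level of 5 reads was 3.68 units in CK1, 4.13 in CK3, 1.51 in T1 and 1.76 in T3, so an entry below it in an unfed library could have been listed only in the fed ones.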

Other observations

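Among families outside the fixed lists, miR5079 was at 97.1 normalized reads in CK1, 126 in CK3, 215 in T1 and 173 in T3. The family miR5083 was at 41.9, 11.6, 54.5 and 112 in the same order, miR6256 at 19.1, 23.9, 51.5 and 60.6, and miR3630 at 11.8, 4.95, 28.2 and 24.6. The family miR1432 was listed at 0 in CK1 and at 19.8, 15.1 and 21.1 in CK3, T1 and T3. These families were chosen after their values were seen, and none passed the limma test on family totals, where miR6256 had an adjusted p of 0.51.

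The fixed lists held 40.2% of the normalized reads in CK1, 30.5% in CK3, 39.3% in T1 and 40.8% in T3.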
